A study of Mus musculus with 300 samples.

How the data were processed

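The deposited table of the authors was used as it stands: per the submitters' processing notes its values are log2 intensities from RMA in Partek, whose versions were not stated. It holds 45101 probe sets of the Affymetrix Mouse Genome 430 2.0 array for 300 arrays, 75 in each of 4 tissues. Per the labels, RNA was isolated with Qiagen miRNeasy and DNase I, and 100 ng of total RNA was amplified and labelled with NuGEN WT Ovation V2 and Encore biotin reagents. 0 columns of values were left unused, 0 columns were identical, and no array was excluded from the reported comparisons. Median log2 intensity ran over 7.27 to 7.44 in heart, 5.05 to 5.38 in kidney, 6.12 to 6.26 in liver and 4.98 to 5.13 in skeletal muscle, so each tissue was fitted by itself and levels were not compared between tissues.

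Of the probe sets 64 were controls, 34945 named 1 gene, 932 named several and 9160 named none. Gene names came from the gene ID for 34741 probe sets, and 204 kept the symbol of the file. The probe set with the highest mean over the 300 arrays stood for its gene, which gave 18193 genes, 9010 of them with more than 1 probe set. No filter on dim genes was applied. List members without a gene name in this table are not reported here. Among called genes, another probe set of the same gene was called the opposite way for 9, 8 and 14 genes in liver (WY14643, GW501516, rosiglitazone), 0, 4 and 5 in heart, 0, 8 and 0 in kidney, and 0, 0 and 0 in skeletal muscle. Called genes under the 40th percentile of mean intensity numbered 251, 244 and 311 in liver, 29, 106 and 215 in heart, 41, 114 and 31 in kidney, and 5, 18 and 38 in skeletal muscle.

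Groups, days, doses and the number of the mouse were read from the sample labels. The same mouse number in the 4 tissues was taken as the same animal, which gave 75 animals. The deviations of gene levels from the group mean were checked across tissues: the median correlation was 0.0964 to 0.168 between tissues of 1 animal against -0.0269 to -0.016 between animals of a group, and 68 to 75 of the 75 animals were higher with their own number. No array date or batch was used here.

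Each tissue was fitted with limma 3.58.1 (lmFit, then eBayes with trend=TRUE) in R 4.3.3, with 1 mean for each of 12 groups and 63 residual degrees of freedom. A compound was compared with vehicle of the same day, and the 3 day effects were averaged with equal weight. P-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, with calls at an adjusted p under 0.05; changes of at least 1.5-fold (0.58 in log2) were counted beside them. Differences between compounds, between days 15 and 4, and between vehicle groups were contrasts of the same fit. Differences of panel genes between liver and another tissue were computed within animals, from 29 measured of 35 panel genes, over 261 tests. The 44 lists were tested with camera (inter.gene.cor=NA, allow.neg.cor=FALSE), adjusted over 528 tests, and also with a preset correlation of 0.01 and with fry, which asks whether a list moves one way and compares it with no other genes. The number of arrays, 5 treated and 10 vehicle on a day, limits the precision of each value.

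Genes were named by a rule set in advance: per comparison the 6 largest rises and 4 largest falls among called genes with at least 14 of 15 treated arrays on that side of the same-day vehicle mean, the genes of the PPAR target panel, per described list up to 4 members with the largest absolute change and called members of opposite sign, and for differences up to 6 panel genes and 6 others. Predicted genes without a name gave way to the next. Not each gene that the rule admits was printed.

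The clock score was component 1 of the scaled clock genes of a tissue, signed so that Arntl was positive and divided by its standard deviation, and was averaged over the tissues of an animal. Components 1 and 2 served as covariates and held 58.5 and 14.4 percent of the variance of clock genes in liver, 57.1 and 17.7 in heart, 42.3 and 18.6 in kidney and 42.2 and 17.7 in skeletal muscle. Marker scores were means of marker genes of other cell types. Correlations were Pearson's r and Spearman's rho with one-sided permutation p, for values as high or higher, from 100000 permutations. Covariances and correlations of fold changes were computed with separate vehicle arrays for each compound, with all of them, and on simulated compounds without effect.

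The fit was tested on data simulated from vehicle means and residual spreads, with 50 genes changed per fold size. For the mean over days, genes changed 1.25, 1.5, 2 and 4-fold were recovered at 84, 94, 100 and 100 percent in liver, 86, 92, 98 and 100 in heart, 72, 98, 100 and 100 in kidney, and 62, 88, 94 and 100 in skeletal muscle. On day 4 these were 44, 74, 98 and 100 in liver, 50, 86, 98 and 98 in heart, 28, 80, 98 and 100 in kidney, and 28, 68, 84 and 98 in skeletal muscle. For WY14643 minus GW501516 they were 74, 88, 100 and 100, then 76, 90, 98 and 98, then 56, 94, 100 and 100, then 54, 86, 92 and 100 in the same order of tissues. With clock components they were 80, 92, 100 and 100, then 78, 92, 98 and 98, then 74, 98, 100 and 100, then 64, 88, 94 and 100. Simulated comparisons gave 5 to 12 false calls each, or 0 without a change. No overlap of clock and treatment and no odd array was simulated, so power and false calls under them were not tested. The simulated list and panel and 0 other lists were called, as were 74 of 87 simulated panel differences between tissues and 6 not simulated.

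Alternatives set in advance were quantile normalization, dim genes left out, the replicate block, each array left out in turn, the mean of the probe sets of a gene, only the 2 treatments compared, array weights, the median of each array subtracted, unpaired tissue differences, all vehicle arrays for both compounds, the preset correlation and fry. Those added later were days 4 and 15 only, clock components or marker scores as covariates and lists without 2 odd arrays. Software beside limma was data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.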

Results

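The series follows 3 agonists of the PPAR nuclear receptors, given by mouth at 10 mg/kg, through liver, heart, kidney and skeletal muscle of the same mice. WY14643 binds PPAR-alpha, GW501516 binds PPAR-delta and rosiglitazone binds PPAR-gamma. In each tissue the 15 arrays of a compound, 5 on each of days 4, 8 and 15, were set against 30 vehicle arrays, 10 on each day. The replicates behind every p-value are separate animals. Sizes are log2 fold changes with standard errors, averaged over the 3 days unless a day is named. A gene was called at an adjusted p under 0.05 in limma, over 18193 genes. The comparisons, the gene lists, the PPAR target panel and the rule for naming genes were fixed before the data were examined. Covariates built from clock genes or from marker genes, the fit without day 8 and the list tests without 2 odd arrays were added after the results were seen.

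In liver, the largest rises with WY14643 were in Cyp4a14 (5.67 ± 0.48), a fatty acid omega-hydroxylase whose vehicle level was 8.21, and Mogat1 (4.37 ± 0.21), a monoacylglycerol acyltransferase. Vnn1 (3.88 ± 0.17), a pantetheinase, Cyp4a31 (3.38 ± 0.39), the acyl-CoA thioesterase Acot3 (3.16 ± 0.37) and the cytochrome oxidase subunit Cox6b2 (3.15 ± 0.25) followed. Ptgds, which makes prostaglandin D2 (-2.70 ± 0.31), the adipokine gene Serpina12 (-2.34 ± 0.20), the odorant-binding protein gene Obp2a (-2.20 ± 0.49) and the adhesion receptor gene Adgrv1 (-1.69 ± 0.22) fell most. These 10 genes lay on the stated side of the same-day vehicle mean in all 15 treated arrays, with adjusted p from 2.41e-29 to 0.000963.

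Of the 29 measured genes of the PPAR target panel, 19 rose with WY14643 in liver, 0 fell and 10 did not pass (22 up and 1 down when adjusted over the list alone; adjusted p = 5.93e-08 for the list with an estimated correlation). Beside those above, the panel rises included the fatty acid translocase Cd36 (2.46 ± 0.17), the adipocyte fatty acid carrier Fabp4 (1.97 ± 0.16), the peroxisomal bifunctional enzyme Ehhadh (1.89 ± 0.056), the transporter Slc27a1 (0.79 ± 0.10), the lipid droplet gene Cidec (0.72 ± 0.15), the dehydrogenase gene Acadl (0.56 ± 0.032) and Pex11a, a gene of peroxisome growth (0.54 ± 0.068). Pdk4 (0.55, adjusted p 0.0953), Cpt1a (0.18, adjusted p 0.136), Angptl4 (0.10, adjusted p 0.713) and Fgf21 (-0.42, adjusted p 0.168) did not pass. Mitochondrial fatty acid oxidation had 23 of 29 genes up (27 over the list alone), with the isomerase Eci1 (0.72 ± 0.038), the carnitine carrier Slc22a5 (0.70 ± 0.091) and Acadm (0.59 ± 0.034) among them. Peroxisomal genes were 17 up and 3 down of 45 (18 and 4 over the list alone), led by the transporter Abcd2 (1.59 ± 0.26) and the carnitine acetyltransferase Crat (1.10 ± 0.11). Fatty acid uptake genes were 9 up and 2 down of 22 (10 and 2 over the list alone), with the lipoprotein receptor Vldlr at 1.25 ± 0.21.

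Outside these lists, liver genes moved both ways with WY14643. Bile acid genes were 8 down and 1 up of 23 (10 and 3 over the list alone; adjusted p = 0.385 for the list with an estimated correlation), with the hydroxylase Cyp39a1 at -0.84 ± 0.22, the uptake carriers Slco1a1 (-0.32 ± 0.073) and Slc10a1 (-0.23 ± 0.035), and the exporter Abcc3 on the other side (0.57 ± 0.084). Xenobiotic genes were 9 down and 5 up of 24 (9 and 8 over the list alone; adjusted p = 0.847 with an estimated correlation): Cyp2c54 (-0.88 ± 0.13) and Cyp2c50 (-0.82 ± 0.11) fell, while Cyp2b9 (2.16 ± 0.55) and Cyp3a13 (0.86 ± 0.12) rose. The phosphatase G6pc of glucose release (-0.74 ± 0.11), the pyruvate kinase gene Pklr (-0.57 ± 0.077), the apolipoprotein gene Apoa4 (-1.09 ± 0.13), the glutathione transferase gene Gstm2 (-0.99 ± 0.13) and the complement gene C8b (-0.45 ± 0.046) fell, and the bisphosphatase gene Fbp2 rose (1.21 ± 0.13). In all, WY14643 changed 2044 liver genes, 1003 up and 1041 down, 230 of them by at least 1.5-fold. Probe sets of the Cyp4a, Cyp2c, Acot and Gstm families, whose members are nearly alike, could not be assigned to one member with certainty.

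With GW501516 in liver, Cyp4a14 (5.48 ± 0.48), Acot3 (4.24 ± 0.37), Vnn1 (3.35 ± 0.17), Mogat1 (2.89 ± 0.21), the DNA repair gene Rad51b (2.84 ± 0.23) and the thioesterase gene Acot1 (2.80 ± 0.19) rose most. Ptgds (-2.15 ± 0.31), the calcium pump gene Atp2b2 (-1.87 ± 0.23), the adaptor gene Nckap5 (-1.83 ± 0.15) and the monooxygenase gene Moxd1 (-1.77 ± 0.51) fell most, each in at least 14 of 15 treated arrays. The panel had 17 genes up and 0 down (19 and 0 over the list alone; adjusted p = 1.7e-06 with an estimated correlation), among them Ehhadh (1.56 ± 0.056), Acot2 (1.84 ± 0.13), Cd36 (1.27 ± 0.17), Pex11a (0.67 ± 0.068), Cidec (0.66 ± 0.15) and the carnitine palmitoyltransferase gene Cpt1a (0.52 ± 0.076). Mitochondrial fatty acid oxidation was 23 of 29 up (25 over the list alone), with Slc22a5 at 0.77 ± 0.091 and Eci1 at 0.68 ± 0.038. Peroxisomal genes were 20 up and 1 down of 45 (23 and 1 over the list alone), with Abcd2 at 1.83 ± 0.26 and Acot4 at 1.40 ± 0.17. Lipid droplet and lipolysis genes were 8 up and 2 down of 24 (10 and 5 over the list alone; adjusted p = 0.245 with an estimated correlation), with the triglyceride lipase gene Pnpla2 (0.61 ± 0.074), Fitm2 (0.55 ± 0.052) and the monoglyceride lipase gene Mgll (0.47 ± 0.059), whereas the acyl-CoA synthetase gene Acsl6 fell (-0.54 ± 0.12).

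Cholesterol synthesis had 9 of 20 genes up with GW501516 in liver (12 over the list alone; adjusted p = 0.518 with an estimated correlation), with Cyp51 at 0.41 ± 0.088. Clock genes were 8 up and 4 down of 17, with Arntl at -1.70 ± 0.23 and Ciart at 1.65 ± 0.23. G6pc (-0.97 ± 0.11), the histidine lyase gene Hal (-0.49 ± 0.051) and Cyp2c55 (-1.21 ± 0.21) fell, and the xenobiotic receptor gene Nr1i3 rose (0.82 ± 0.077). GW501516 changed 2532 liver genes, 1248 up and 1284 down, 227 by at least 1.5-fold. With clock components as covariates 485 genes were called, and the calls of Atp2b2, Moxd1, Cpt1a and Ciart ended. Without day 8 the count was 1344.

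Rosiglitazone raised Acot3 (3.54 ± 0.37), Vnn1 (2.36 ± 0.17), the growth factor gene Nrg4 (1.73 ± 0.19), the phosphatase gene Pdxp (1.71 ± 0.19), the deubiquitinase gene Usp2 (1.69 ± 0.20) and Acot1 (1.66 ± 0.19) most in liver. Nckap5 (-1.83 ± 0.15), the clock gene Arntl (-1.52 ± 0.23), Asap2, which acts in vesicle traffic (-1.43 ± 0.14), and Atp2b2 (-1.37 ± 0.23) fell most. The panel had 13 genes up and 0 down (15 and 1 over the list alone; adjusted p = 0.0144 with an estimated correlation), with Cidec (1.16 ± 0.15), Pex11a (0.66 ± 0.068), the arrestin-like gene Txnip (0.60 ± 0.12) and Cpt1a (0.42 ± 0.076) among them, and Cyp4a14 not passing (0.73, adjusted p 0.34). Lipid droplet genes were 10 up and 4 down of 24 (14 and 6 over the list alone), with the droplet coat gene Plin4 at 1.15 ± 0.18, the lipase inhibitor gene G0s2 at 0.94 ± 0.21 and Pnpla3 at -1.03 ± 0.34. These were the 2 lists called, and camera called 0 with clock components as covariates or with dim genes left out. Cholesterol synthesis had 10 of 20 genes down (15 over the list alone; adjusted p = 0.546 with an estimated correlation), among them Mvd (-0.88 ± 0.19) and Sqle (-0.54 ± 0.15). Fasn, the fatty acid synthase gene (-0.53 ± 0.13), the urea cycle gene Ass1 (-0.87 ± 0.17) and the bile acid exporter gene Slc51b (-0.95 ± 0.19) fell, while Cyp2b10 (1.19 ± 0.35) and the glucocorticoid-inducible Fkbp5 (1.55 ± 0.15) rose. Clock genes were 8 up and 4 down of 17.

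Rosiglitazone changed 2946 liver genes, 1361 up and 1585 down, 219 by at least 1.5-fold. Clock components as covariates gave 31 genes and 2 panel genes. The score and the treatment overlap: over the 2946 genes the median absolute change went from 0.236 to 0.113 and the median standard error from 0.0592 to 0.119. Of the genes named for rosiglitazone in liver Vnn1 and Cidec kept their calls while the signs of Mvd, Sqle and Cyp2b10 turned. Without day 8 the count was 1823, and the calls of Arntl, Cpt1a, Pnpla3 and Fasn ended.

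At the matched dose of 10 mg/kg in liver, WY14643 raised Cyp4a14 by 4.95 more than rosiglitazone (95% interval 3.85 to 6.05), Mogat1 by 3.12 (2.65 to 3.60), Cd36 by 1.91 (1.51 to 2.31) and Ehhadh by 1.71 (1.58 to 1.84). Against GW501516, WY14643 gave more Cox6b2 (1.69 (1.12 to 2.26)), the epithelial gene Ly6d (1.69 (1.06 to 2.31)), the laminin gene Lamb3 (1.57 (1.33 to 1.82)), Fabp4 (1.52 (1.16 to 1.88)) and Cd36 (1.19 (0.79 to 1.59)), and less Cpt1a (-0.35 (-0.52 to -0.17)). Cyp4a14 did not differ between WY14643 and GW501516 (0.20 (-0.91 to 1.30)). GW501516 exceeded rosiglitazone for Cyp4a14 (4.75 (3.65 to 5.85)), Rad51b (2.48 (1.94 to 3.02)), Abcd2 (1.63 (1.03 to 2.22)) and Ehhadh (1.38 (1.25 to 1.51)). Over all genes, WY14643 differed at 827 from GW501516 and 3199 from rosiglitazone, and GW501516 at 653 from rosiglitazone. In the panel 4 genes were higher and 1 lower with WY14643 than with GW501516, 15 and 2 against rosiglitazone, and 11 and 0 for GW501516 against rosiglitazone.

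**Figure D1:**
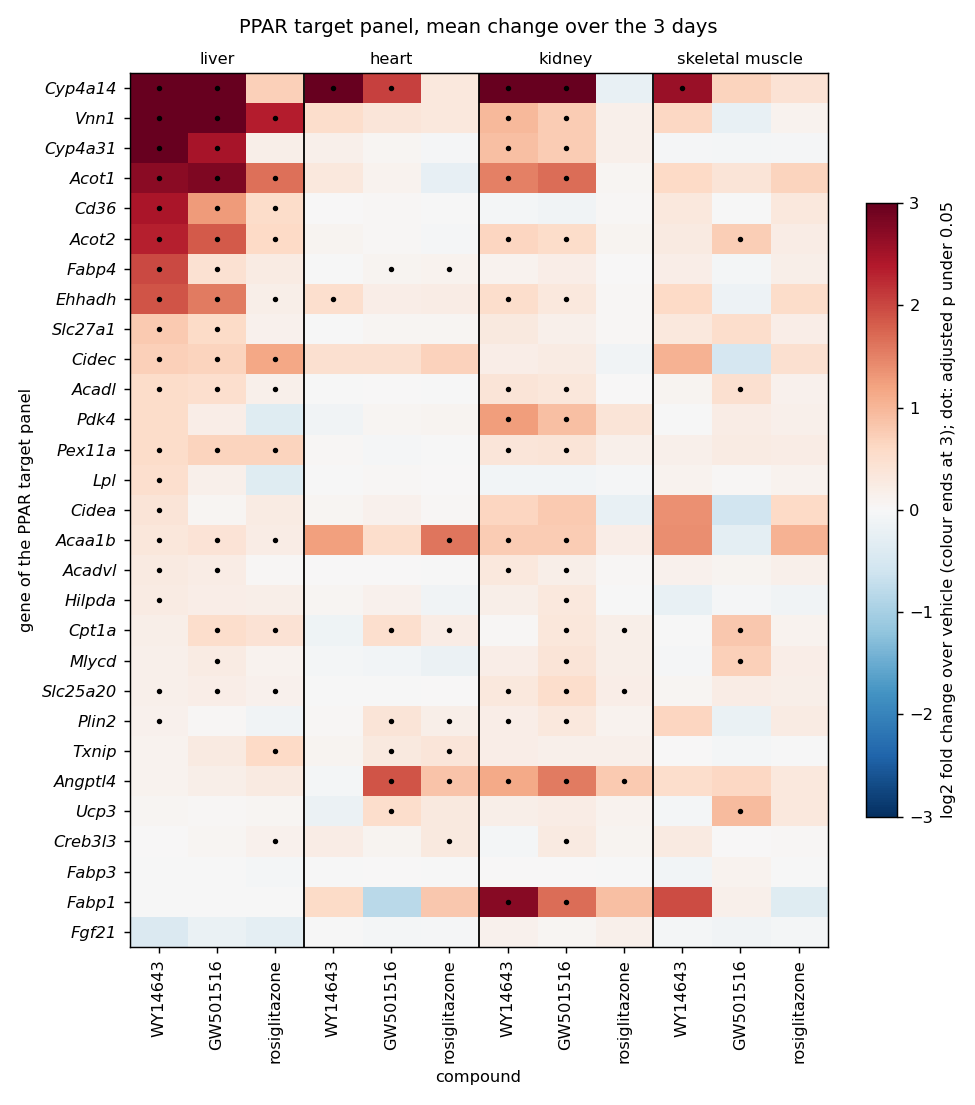
Heatmap of log2 fold change against vehicle, averaged over the 3 days, for the 29 measured PPAR target genes (vertical) in each of the 12 combinations of tissue and compound (horizontal), with a dot where adjusted p was under 0.05. WY14643 raised 19 panel genes in liver and 15 in kidney, against 2 in heart and 1 in skeletal muscle.

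In heart, WY14643 raised Cyp4a14 (4.03 ± 0.34, in 14 of 15 arrays) most. The chemokine genes Ccl12 (1.0 ± 0.21) and Ccl9 (0.59 ± 0.11), the monocyte gene Ms4a6c (0.58 ± 0.10), the kinase gene Map3k6 (0.65 ± 0.13) and Timp4 (0.64 ± 0.10) followed Cyp4a14. The anchoring protein gene Akap5 (-0.74 ± 0.15) and the transcription factor gene Sox4 (-0.50 ± 0.10) fell, as did Cyp26b1, which clears retinoic acid (-0.74 ± 0.21), and the Wnt modulator gene Sfrp2 (-0.55 ± 0.15). Among 9 neutrophil genes 4 rose (7 over the list alone; adjusted p = 0.0783 with an estimated correlation), with S100a8 at 1.20 ± 0.27 and S100a9 at 1.02 ± 0.24; replicate 2 of day 4 held the highest mean of these genes, 9.76 against a median of 6.21 over all hearts. Unfolded protein response genes had 4 of 23 up (9 over the list alone; adjusted p = 0.0239 with an estimated correlation), with the endoplasmic reticulum gene Sdf2l1 at 0.45 ± 0.076 and Creld2 at 0.22 ± 0.048. This was the 1 list called there; 9 of 100 splits of the samples called as many, and 0 lists were called by camera with clock components as covariates. The panel had 2 genes up, Cyp4a14 and Ehhadh (0.49 ± 0.13), and 0 down (2 up over the list alone; adjusted p = 0.47 with an estimated correlation).

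WY14643 changed 262 heart genes, 110 up and 152 down, 21 by at least 1.5-fold. The count was 113 without replicate 2 of day 4, 455 without vehicle replicate 8 of day 15, 174 with clock components as covariates and 680 with array weights. The calls of Cyp26b1, Sfrp2 and Ehhadh ended when any of 22, 18 and 6 of the 45 single arrays were left out, and theirs and that of Sox4 without day 8. Cyp4a14 went with hepatocyte markers in heart: over the 15 WY14643 arrays, deviations from the group means gave r 0.951 (one-sided permutation p 0.00019, 0.00028 after Benjamini-Hochberg over 3 tissues), rho 0.971 (permutation p 1e-05), and r 0.911 without the 2 farthest arrays. The mean of these markers ran from 5.70 to 11.8 over all heart arrays and from 5.91 to 11.7 over vehicle hearts.

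In heart, with GW501516, Angptl4, an inhibitor of lipoprotein lipase (1.90 ± 0.20), the transcription factor genes Tcf23 (1.23 ± 0.14) and Zbtb16 (0.86 ± 0.085), Tent5b (1.01 ± 0.16), Fam107a (0.98 ± 0.17) and Angptl7 (0.94 ± 0.18) rose most. The immediate early gene Fos (-1.69 ± 0.26), the brain-type fatty acid carrier Fabp7 (-1.03 ± 0.17), the chaperone gene Dnajb1 (-0.69 ± 0.13) and Ddit4l (-0.65 ± 0.10) fell most. The panel had 7 genes up and 0 down (9 and 0 over the list alone; adjusted p = 0.00303 with an estimated correlation), with Cyp4a14 at 2.04 ± 0.34, Cpt1a at 0.49 ± 0.054, the droplet coat gene Plin2 at 0.40 ± 0.054, Txnip at 0.30 ± 0.053 and the uncoupling protein gene Ucp3 at 0.52 ± 0.14 in 10 of 15 arrays. Over the 15 GW501516 arrays Cyp4a14 went with hepatocyte markers (r 0.942, one-sided permutation p 1e-05, the smallest that 100000 permutations can give; 2e-05 after Benjamini-Hochberg over heart and kidney; rho 0.914; r 0.883 without the 2 farthest arrays). The panel was the 1 list called; 5 of 100 splits called as many and up to 6, and with clock components as covariates camera called 0. The glutathione transferase gene Gstt2 (0.54 ± 0.07), the epoxide hydrolase gene Ephx1 (0.31 ± 0.047) and the cholesterol exporter gene Abca1 (0.25 ± 0.049) rose, whereas the thermogenic regulator gene Prdm16 fell (-0.31 ± 0.064). Clock genes were 8 up and 2 down of 17 (9 and 6 over the list alone), with Arntl at -1.33 ± 0.15 and Per3 at 0.54 ± 0.081. GW501516 changed 759 heart genes, 335 up and 424 down, 38 by at least 1.5-fold. The count was 221 with clock components as covariates, which ended the calls of Tent5b, Fam107a, Angptl7, Fabp7, Cyp4a14, Ucp3, Abca1, Arntl and Per3, 202 without day 8 and 1267 with array weights.

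In heart, rosiglitazone changed many genes while camera called 0 of 44 lists. The membrane protein gene Ctxn3 (1.40 ± 0.15), Angptl7 (1.35 ± 0.18), Fam107a (1.28 ± 0.17), Tent5b (1.10 ± 0.16), the alcohol dehydrogenase gene Adh1 (1.09 ± 0.12) and Zbtb16 (1.04 ± 0.085) rose most. Arntl (-1.71 ± 0.15), the heat shock gene Hspa1a (-1.33 ± 0.44), Fabp7 (-1.17 ± 0.17) and the protease gene Adamts4 (-1.03 ± 0.18) fell most. The panel had 7 genes up and 0 down (7 and 1 over the list alone; adjusted p = 0.243 with an estimated correlation), among them the thiolase gene Acaa1b (1.61 ± 0.43), Angptl4 (0.86 ± 0.20), Txnip (0.36 ± 0.053), Cpt1a (0.23 ± 0.054) and Fabp4 (0.10 ± 0.019). The nuclear receptor gene Pparg (0.39 ± 0.086), the acyltransferase gene Dgat2 (0.23 ± 0.028), the glutathione transferase gene Gsta3 (1.03 ± 0.10) and Ephx1 (0.33 ± 0.047) rose, while the collagen gene Col1a1 (-0.46 ± 0.11), the calcineurin regulator Rcan1 (-0.43 ± 0.062) and the red cell anion exchanger Slc4a1 (-0.81 ± 0.19) fell. Rosiglitazone changed 1367 heart genes, 499 up and 868 down, 80 by at least 1.5-fold, 399 without day 8 and 2070 with array weights. Adipocyte markers averaged 9.13, 8.77 and 8.69 on days 4, 8 and 15 with rosiglitazone against 8.18, 8.51 and 8.59 with vehicle, and hepatocyte markers 11.01 against 9.73 on day 15; without replicate 1 of day 4, which held an adipocyte mean of 12.4, Pparg was at 0.26. Clock components as covariates gave 251 genes and 2 panel genes; of the genes named for rosiglitazone in heart, Txnip, Fabp4, Ephx1 and Hspa1a kept their calls while the signs of Fabp7, Rcan1 and Col1a1 turned. The call of Hspa1a ended when any of 28 of the 45 single arrays were left out.

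In heart at matched dose, GW501516 gave more Angptl4 than WY14643 (WY14643 minus GW501516 -1.95 (-2.42 to -1.48)), more Cpt1a (-0.61 (-0.74 to -0.49)) and more Ucp3 (-0.69 (-1.0 to -0.37)), and less Cyp4a14 (1.98 (1.19 to 2.78)). WY14643 exceeded rosiglitazone for Cyp4a14 (3.70 (2.91 to 4.50)), S100a8 (1.82 (1.20 to 2.44)) and Arntl (1.64 (1.28 to 1.99)). GW501516 and rosiglitazone differed at 8 genes, among them Ctxn3 (-0.87 (-1.22 to -0.52)), Gsta3 (-0.76 (-0.98 to -0.53)) and the myeloid receptor gene Cd300a (0.66 (0.51 to 0.82)), and at 0 of the 29 panel genes. Cyp4a14 went with hepatocyte markers in these hearts. The counts for WY14643 were 552 against GW501516 and 1114 against rosiglitazone.

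In kidney, WY14643 raised Cyp4a14 (5.76 ± 0.27; vehicle level 6.85), the liver-type fatty acid carrier gene Fabp1 (2.73 ± 0.50), the retinal dehydrogenase gene Aldh1a1 (1.96 ± 0.33), Acot1 (1.52 ± 0.16), Cox6b2 (1.48 ± 0.087) and Zbtb16 (1.39 ± 0.22) most. The mitotic spindle gene Aspm (-0.93 ± 0.12), the lipid-binding gene Sec14l3 (-0.76 ± 0.11), the replication gene Mcm10 (-0.72 ± 0.11) and the collagen gene Col19a1 (-0.62 ± 0.13) fell most. The panel had 15 genes up and 0 down (17 and 0 over the list alone; adjusted p = 1.16e-09 with an estimated correlation), with the dehydrogenase kinase gene Pdk4 (1.26 ± 0.14), Angptl4 (1.14 ± 0.14), Vnn1 (0.98 ± 0.079), Acaa1b (0.75 ± 0.06) and Ehhadh (0.54 ± 0.053) among them. Mitochondrial fatty acid oxidation was 16 of 29 up (17 over the list alone), with Eci1 at 0.80 ± 0.067 and Acaa2 at 0.63 ± 0.079. Peroxisomal genes had 11 of 45 up (14 up and 3 down over the list alone), with Acot3 at 1.35 ± 0.19 and Hacl1, a lyase of alpha-oxidation, at 0.50 ± 0.088. Cholesterol synthesis was 6 up and 1 down of 20 (13 and 1 over the list alone; adjusted p = 0.00243 with an estimated correlation), with Sqle at 0.43 ± 0.071. Cell cycle genes had 7 of 35 down (13 over the list alone; adjusted p = 0.0338 with an estimated correlation), with Ccnb2 at -0.50 ± 0.10 and Ccna2 at -0.43 ± 0.077.

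WY14643 changed 316 kidney genes, 168 up and 148 down, 45 by at least 1.5-fold. The count was 175 without day 8, where the calls of Fabp1 and Zbtb16 ended, and 634 with array weights. The 8 lists called became 5 with clock components as covariates, 5 with the replicate block and 5 without the odd arrays. Replicate 2 of day 4 stood apart, with a panel mean of 10.1 against 9.30 to 9.36 in the rest of its group. Cyp4a14 did not follow hepatocyte markers here (r -0.00535, one-sided permutation p 0.51; rho 0.0715, permutation p 0.39; r 0.0988 without the 2 farthest; 0.51 after Benjamini-Hochberg over 3 tissues).

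With GW501516 in kidney, Cyp4a14 (3.78 ± 0.27), the proton pump gene Atp12a (1.88 ± 0.20), Acot1 (1.68 ± 0.16), Angptl4 (1.55 ± 0.14), Acot3 (1.49 ± 0.19) and Nkain1, which binds the sodium pump (1.26 ± 0.10), rose most. Hspa1a (-0.93 ± 0.30), the repressor gene Bcl6b (-0.76 ± 0.13), Noxred1 (-0.69 ± 0.14) and the lipoprotein receptor gene Lrp12 (-0.68 ± 0.12) fell most. The panel had 19 genes up and 0 down (20 and 0 over the list alone; adjusted p = 3.88e-07 with an estimated correlation), with Pdk4 (0.91 ± 0.14), the carnitine carrier Slc25a20 (0.53 ± 0.048), the decarboxylase gene Mlycd (0.40 ± 0.056) and Cpt1a (0.35 ± 0.035) among them. Peroxisomal genes were 18 up and 1 down of 45 (20 and 1 over the list alone), with Eci2 at 0.46 ± 0.041 and Acot4 at 0.44 ± 0.091. Mitochondrial fatty acid oxidation was 17 of 29 up (20 over the list alone), with Cpt2 at 0.56 ± 0.056 and Eci1 at 0.80 ± 0.067. Lipid droplet genes were 10 of 24 up (12 over the list alone), with Mgll at 0.87 ± 0.061, Plin5 at 0.69 ± 0.093 and G0s2 at 0.66 ± 0.12. The regulator gene Srebf1 (0.45 ± 0.072), the lipoprotein assembly gene Mttp (0.46 ± 0.074), Abca1 (0.45 ± 0.091) and the monocyte gene Cd14 (0.53 ± 0.10) rose. Clock genes were 4 up and 4 down of 17 (7 and 4 over the list alone), with Npas2 at -1.30 ± 0.19 and Cry1 at 1.14 ± 0.12.

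GW501516 changed 1236 kidney genes, 717 up and 519 down, 53 by at least 1.5-fold, and 321 without day 8, where the calls of Bcl6b and Npas2 ended. The call of Hspa1a ended when any of 17 of the 45 single arrays were left out. Cyp4a14 did not rise with hepatocyte markers over the 15 GW501516 arrays (r -0.682, one-sided permutation p 0.99; rho -0.568; r -0.87 without the 2 farthest; 0.99 after Benjamini-Hochberg over heart and kidney).

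With rosiglitazone in kidney, Zbtb16 (1.77 ± 0.22), Cry1 (1.67 ± 0.12), the growth factor gene Fgf18 (0.89 ± 0.16), Angptl4 (0.79 ± 0.14), Id1 (0.74 ± 0.11) and Nfil3 (0.69 ± 0.15) rose most, and Adamts4 (-0.87 ± 0.16), the axon guidance gene Nav3 (-0.81 ± 0.18), the clock repressor gene Nr1d1 (-0.80 ± 0.10) and Bcl6b (-0.63 ± 0.13) fell most. Glucocorticoid-inducible genes had 6 of 15 up (9 up and 1 down over the list alone; adjusted p = 0.00247 with an estimated correlation), with Tsc22d3 at 0.48 ± 0.11 and the phosphatase gene Dusp1 at 0.48 ± 0.073. Peroxisomal genes had 0 of 45 called (8 up over the list alone) while the list as a whole was higher than other genes (adjusted p = 0.021 with an estimated correlation). G6pc (0.34 ± 0.051) and Pck1 (0.27 ± 0.049), both of glucose synthesis, and Ppara (0.33 ± 0.077) rose, and the cholesterol gene Idi1 (-0.32 ± 0.073) and Ccna2 (-0.45 ± 0.077) fell. The panel had 3 genes up, Angptl4, Slc25a20 (0.20 ± 0.048) and Cpt1a (0.18 ± 0.035), and 0 down (7 and 0 over the list alone; adjusted p = 0.0811 with an estimated correlation). Rosiglitazone changed 276 kidney genes, 165 up and 111 down, 22 by at least 1.5-fold. Without day 8 the count was 29, and with array weights 737. Of the 2 lists called, 1 was called with clock components as covariates, and 5 of 100 splits called as many as 2. With clock components as covariates, 0 panel genes were called, and of the genes named for rosiglitazone in kidney Cry1, Adamts4, Nr1d1, Dusp1 and G6pc kept their calls while the signs of Nfil3, Ppara and Tsc22d3 turned.

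At matched dose in kidney, WY14643 gave less Atp12a than GW501516 (-2.41 (-2.87 to -1.95)) and less Cpt1a (-0.32 (-0.40 to -0.24)), but more Cyp4a14 (1.98 (1.36 to 2.61)) and Aldh1a1 (1.59 (0.82 to 2.35)). Against rosiglitazone, WY14643 gave more Cyp4a14 (5.98 (5.36 to 6.61)), Acot1 (1.47 (1.11 to 1.83)), Cox6b2 (1.42 (1.22 to 1.62)) and Pdk4 (0.87 (0.54 to 1.20)), and GW501516 gave more Cyp4a14 (4.0 (3.37 to 4.63)), Atp12a (2.22 (1.76 to 2.68)) and Angptl4 (0.76 (0.44 to 1.08)). WY14643 differed at 244 genes from GW501516 and 355 from rosiglitazone, and GW501516 at 203 from rosiglitazone. In the panel, 11 genes were higher and 1 lower with WY14643 than with rosiglitazone, and 12 and 0 with GW501516.

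In skeletal muscle, camera called 0 of 44 lists for GW501516. Fbp2, the muscle fructose bisphosphatase gene (1.48 ± 0.11), rose most, with Fam107a (1.01 ± 0.18), Ucp3 (0.95 ± 0.12), Cpt1a (0.81 ± 0.12), the carbonic anhydrase gene Car9 (0.81 ± 0.13) and the developmental gene Hoxa4 (0.75 ± 0.10). Apold1, a vascular early response gene (-1.72 ± 0.20), the orphan receptor gene Nr4a2 (-1.25 ± 0.23), Bcl6b (-1.21 ± 0.14) and Fos (-1.13 ± 0.24) fell most. The panel had 5 genes up and 0 down (7 and 0 over the list alone; adjusted p = 0.325 with an estimated correlation), with Acot2 (0.75 ± 0.13), Mlycd (0.71 ± 0.077) and Acadl (0.48 ± 0.12) beside Ucp3 and Cpt1a. Mitochondrial fatty acid oxidation had 5 of 29 genes up (6 over the list alone; adjusted p = 0.443 with an estimated correlation), and the peroxisomal isomerase gene Eci2 rose (0.50 ± 0.07). The chaperone gene Dnajb1 fell (-0.87 ± 0.16) and Zbtb16 rose (0.49 ± 0.072). Clock genes were 2 up and 3 down of 17 (5 and 4 over the list alone), with Per2 at 0.84 ± 0.14 and Nr1d1 at -0.49 ± 0.11. GW501516 changed 156 muscle genes, 83 up and 73 down, 33 by at least 1.5-fold; the count was 53 with clock components as covariates, which ended the calls of Fam107a, Fos, Per2 and Nr1d1, 26 without day 8, where that of Acadl ended too, and 458 with array weights.

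Rosiglitazone raised Fam107a (1.35 ± 0.18), Adh1 (0.94 ± 0.12), the ubiquitin ligase gene Hecw2 (0.94 ± 0.12), Timp4 (0.93 ± 0.10), Lonrf3 (0.91 ± 0.17) and Map3k6 (0.87 ± 0.15) most in muscle, and lowered Apold1 (-1.44 ± 0.20), Bcl6b (-1.26 ± 0.14), Nr4a2 (-1.15 ± 0.23) and Fos (-1.11 ± 0.24) most. Gpihbp1, which holds lipoprotein lipase on capillaries (0.52 ± 0.089), the proline dehydrogenase gene Prodh (0.60 ± 0.10), the lipogenic regulator Mid1ip1 (0.46 ± 0.083) and Zbtb16 (0.63 ± 0.072) also rose, and Nr1d1 (-0.87 ± 0.11) and Clock (-0.36 ± 0.046) fell. The panel had 0 genes called over all genes. Rosiglitazone changed 301 muscle genes, 114 up and 187 down, 50 by at least 1.5-fold. The count was 84 with clock components as covariates, which ended the calls of Lonrf3, Map3k6, Fos, Prodh and Clock, 16 without day 8, where those of Fam107a, Apold1, Nr4a2 and Mid1ip1 ended too, and 643 with array weights.

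WY14643 changed 19 muscle genes, 9 up and 10 down, 9 of the 19 by at least 1.5-fold. Cyp4a14 (2.59 ± 0.35, in 14 of 15 arrays; its vehicle level of 2.17 lay near the 5th percentile of the arrays, 1.52 to 1.74, so the size depends on the background), Fam107a (1.07 ± 0.18), Timp4 (0.70 ± 0.10), the exchange factor gene Mcf2l (0.59 ± 0.10) and the sphingosine receptor gene S1pr4 (0.39 ± 0.085) rose, and Bcl6b (-1.02 ± 0.14), Mycn (-0.70 ± 0.12), the cell death gene Bcl2l11 (-0.44 ± 0.10) and the arrestin-like gene Arrdc4 (-0.39 ± 0.087) fell. Cyp4a14 was the 1 panel gene up, with 0 down (1 and 1 over the list alone; adjusted p = 0.441 with an estimated correlation). Leaving out single arrays moved the count of 19 between 10 and 81. Without day 8 the calls of Fam107a and Mcf2l ended, and with the mean of its probe sets that of Mycn. Calls of S1pr4, Bcl2l11 and Arrdc4 ended when any of 4, 26 and 14 of the 45 single arrays were left out. Cyp4a14 went with hepatocyte markers in muscle over the 15 WY14643 arrays (deviations from the group means, r 0.989, one-sided permutation p 2e-05, 6e-05 after Benjamini-Hochberg over 3 tissues; rho 0.982, permutation p 2e-05; r 0.978 without the 2 farthest). The mean of these markers ran from 3.86 to 11.3 over all muscle arrays and up to 9.69 in vehicle muscle.

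**Figure D2:**
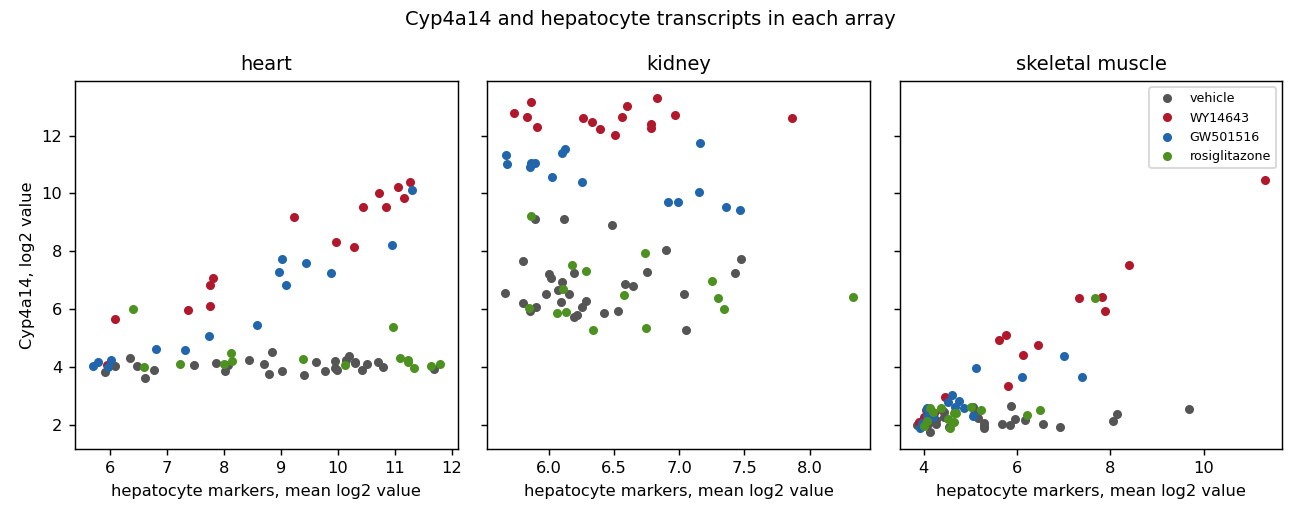
Cyp4a14 (vertical, log2) against the mean of the hepatocyte markers (horizontal, log2) for each array of heart, kidney and skeletal muscle, coloured by treatment. Over the 15 WY14643 arrays of each tissue r was 0.951 in heart and 0.989 in skeletal muscle, against -0.00535 in kidney.

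In muscle, the rise in Fbp2 with GW501516 exceeded that of rosiglitazone by 1.34 (1.09 to 1.59), in Cpt1a by 0.69 (0.42 to 0.97), in Ucp3 by 0.64 (0.36 to 0.93) and in Mlycd by 0.52 (0.34 to 0.70). WY14643 minus GW501516 was -1.42 (-1.68 to -1.17) for Fbp2, -1.0 (-1.29 to -0.72) for Ucp3 and -0.82 (-1.09 to -0.55) for Cpt1a. WY14643 differed at 104 genes from GW501516 and 7 from rosiglitazone, where Nr1d1 (0.72 (0.46 to 0.98)) and Clock (0.34 (0.23 to 0.45)) were higher with WY14643, and GW501516 at 12 from rosiglitazone.

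Of 261 panel differences of liver from other tissues within animals, 48 passed for WY14643, 46 for GW501516 and 33 for rosiglitazone. With WY14643, Vnn1 rose more in liver than in heart (3.35 (2.75 to 3.96)) and kidney (2.90 (2.55 to 3.25)), and Cd36 more than in kidney (2.52 (2.13 to 2.91)). Fabp1 rose in kidney and not in liver (-2.75 (-3.77 to -1.73)), with liver RNA in kidney and signal range in liver not tested. With GW501516, Angptl4 rose less in liver than in heart (-1.73 (-2.12 to -1.34)) or kidney (-1.38 (-1.64 to -1.12)). With rosiglitazone, Acot1 rose more in liver than in kidney (1.61 (1.25 to 1.97)). For WY14643, 17 panel genes were higher and 0 lower in liver than in heart, 11 and 6 against kidney, and 13 and 1 against muscle.

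The circadian clock genes moved with treatment and with day. In liver, WY14643 raised Arntl by 2.04 on day 4 and lowered it by 2.07 on day 8, and 8 of 17 clock genes were called in opposite directions on 2 days, against 0 for GW501516 and 0 for rosiglitazone. GW501516 gave -0.40, -2.68 and -2.02 for Arntl on days 4, 8 and 15, and rosiglitazone 0.28, -3.16 and -1.67. Vehicle liver changed too: Arntl was higher on day 15 than on day 4 (1.68 (1.03 to 2.34)), as was Npas2 (1.60 (0.99 to 2.20)), and Usp2 was lower (-1.40 (-1.95 to -0.85)). The deviation of the clock score from the group mean was shared by the tissues of an animal, with a mean r over tissue pairs of 0.75 (one-sided permutation p 1e-05, the smallest that 100000 permutations can give, rho 0.728, and r 0.763 without the 2 farthest animals). The vehicle group mean of the score was -0.598, 1.35 and 0.633 on days 4, 8 and 15, while GW501516 held -0.634, -0.591 and -0.779.

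**Figure D3:**
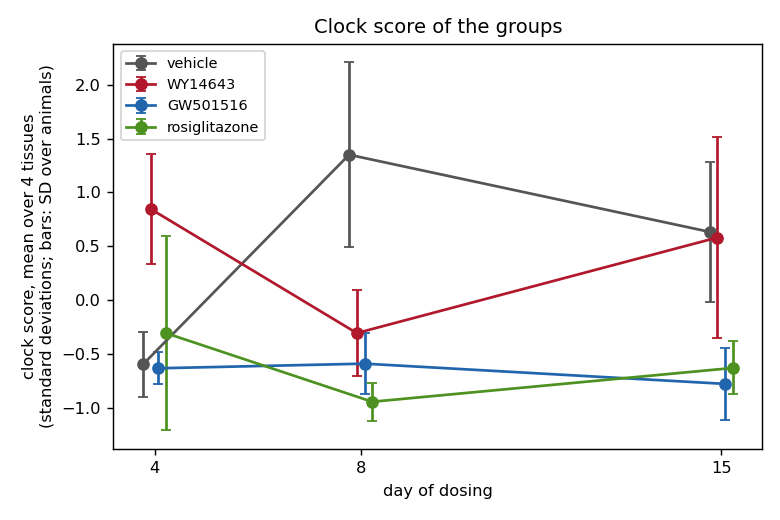
Mean clock score over the 4 tissues (vertical, standard deviations) on days 4, 8 and 15 (horizontal) for each treatment, with points for the mean of the animals and bars for 1 standard deviation. The vehicle mean rose from -0.598 on day 4 to 1.35 on day 8, whereas the GW501516 mean stayed between -0.779 and -0.591.

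Between day 4 and day 15 the WY14643 response of liver fell for Npas2 (-3.12 (-4.17 to -2.07)), Nckap5 (-2.85 (-3.59 to -2.10)) and Arntl (-2.37 (-3.51 to -1.23)) and rose for Pdxp (2.85 (1.91 to 3.78)) and Usp2 (2.59 (1.64 to 3.55)), among 137 genes. That count was 61 without WY14643 day 15 replicate 3 and at most 194 with 1 array left out. With rosiglitazone 24 liver genes passed (2 to 50, without its day 15 replicates 2 and 1 in turn), among them Depp1 (-2.88 (-4.11 to -1.65)) and the panel gene Plin2 (-0.66 (-0.88 to -0.44)), and with GW501516 0 passed in limma (1214 at an unadjusted p under 0.05).
Heart gave 50 genes for WY14643, 11 without its day 15 replicate 4 and 408 without replicate 5, and 17 of 100 splits gave as many, up to 3907. Among the 50 were Fos (2.84 (1.56 to 4.11)), Prr3 (-1.64 (-2.20 to -1.07)) and the collagen gene Col5a3 (-1.44 (-1.95 to -0.94)). Heart gave 3 for GW501516, among them Tnfrsf19 (-0.89 (-1.25 to -0.52)), and 0 for rosiglitazone (1629 at an unadjusted p under 0.05).
Kidney gave 4 for WY14643, Cry1 (1.65 (1.06 to 2.24)), Ier3 (1.31 (0.83 to 1.80)), Mylip (1.12 (0.65 to 1.59)) and Cry2 (0.78 (0.51 to 1.05)), 2 for GW501516, Cry1 (1.53 (0.95 to 2.12)) and Tll1 (1.01 (0.61 to 1.42)), and 0 for rosiglitazone (552 unadjusted).
Muscle gave 0 for WY14643 (1845 unadjusted), 0 for GW501516 (555 unadjusted) and 1 for rosiglitazone, Clock (-0.64 (-0.86 to -0.41)). The vehicle groups themselves differed between days 15 and 4 at 739 genes in liver, 71 in heart, 159 in kidney and 1 in muscle, where Clock rose (0.43 (0.30 to 0.56)).

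The counts by day rested on few animals, 5 treated against 10 vehicle. Vehicle itself moved (clock score -0.598 on day 4, 1.35 on day 8), so a day-8 peak need not come from the compound. On days 4, 8 and 15 liver gave 1173, 1149 and 521 for WY14643 and 245, 1607 and 804 for GW501516. Rosiglitazone gave 224, 2326 and 972. Without 1 array day 4 fell to 672 (WY14643 replicate 2) and 65 (rosiglitazone replicate 5). Heart gave 46, 79 and 613, then 23, 297 and 139, then 40, 760 and 199. Without WY14643 replicate 4 the 613 became 12. Kidney gave 50, 92 and 99, then 31, 1703 and 242, then 0, 137 and 24 (518 unadjusted on rosiglitazone day 4); without GW501516 replicate 1 the 1703 became 137. Muscle gave 608, 7 and 3, then 3, 71 and 12, then 0, 155 and 44 (541 unadjusted on rosiglitazone day 4); without WY14643 replicate 3 the 608 became 149.

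**Figure D4:**
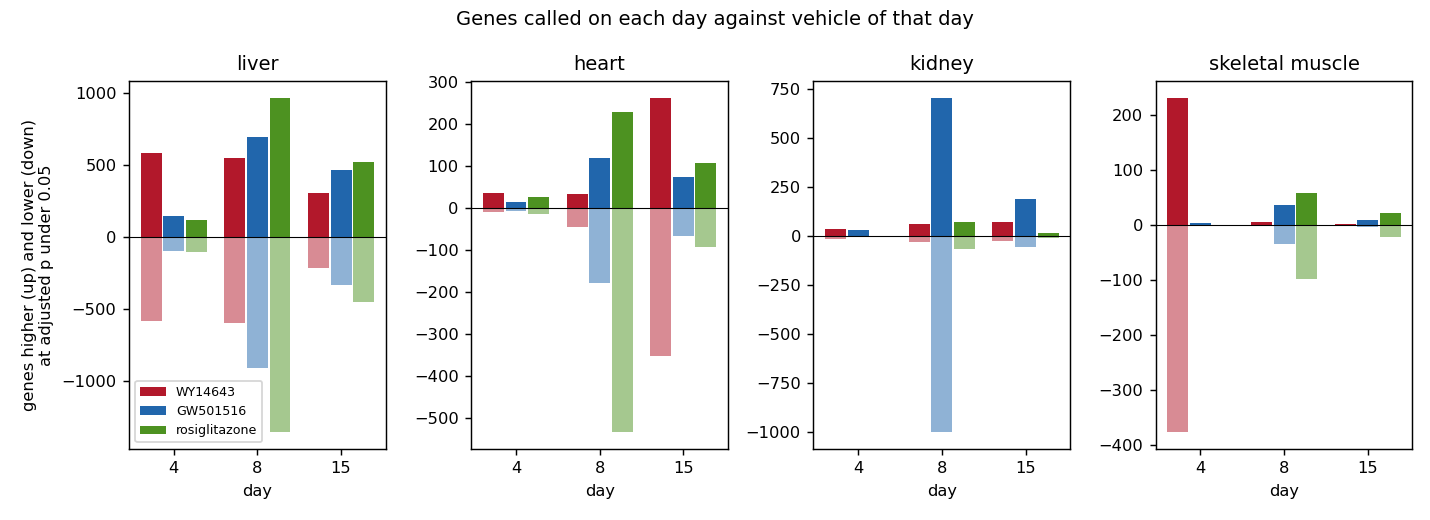
Genes called against same-day vehicle (vertical, number of genes, risen above 0 and fallen below) on days 4, 8 and 15 for each compound (horizontal), in 1 panel per tissue. Liver called 2326 genes with rosiglitazone on day 8 against 224 on day 4, and muscle called 608 with WY14643 on day 4 against 7 on day 8.

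On day 4 of WY14643 in muscle the median change was 3.32 for hepatocyte markers, 1.93 for brown adipocyte and 1.84 for adipocyte markers, against -0.0863 for cardiomyocyte markers. Replicate 3 of that group held the highest hepatocyte (11.3) and brown adipocyte (10.8) marker means of all muscle arrays. In heart, rosiglitazone day 4 replicate 1 held the highest adipocyte (12.4) and lymphocyte (9.26) marker means, and WY14643 day 4 replicate 2 the highest neutrophil mean (9.76), beside the 4 neutrophil genes called there. In kidney, the pancreatic acinar mean reached 11.9 in WY14643 day 4 replicate 2 against a median of 4.15.

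Compounds shared changed genes within a tissue, counted with the same vehicle arrays for each compound, which by itself adds shared calls. In liver, WY14643 and GW501516 shared 504 risen genes and 475 fallen, WY14643 and rosiglitazone 263 and 241, and GW501516 and rosiglitazone 670 and 657. The pairs in this order gave 36 and 34, 43 and 59, and 249 and 328 in heart. Kidney gave 94 and 34, 21 and 17, and 77 and 57. Muscle gave 7 and 5, 8 and 6, and 31 and 44. Across genes, which are not independent replicates, the correlation of fold changes computed against separate vehicle arrays was 0.549 (covariance 0.0217) for WY14643 and GW501516 in liver, 0.178 (0.00668) for WY14643 and rosiglitazone, and 0.491 (0.018) for GW501516 and rosiglitazone. With all vehicle arrays shared the values were 0.685, 0.291 and 0.634, and simulated compounds without effect gave 0.359, 0.317 and 0.33. With separate vehicle arrays the 3 pairs gave 0.164, 0.286 and 0.258 in heart, 0.294, 0.109 and 0.215 in kidney, and -0.153, 0.236 and 0.148 in muscle.

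Lists were also tested with a preset correlation of 0.01. Calls from the preset that held with an estimated correlation numbered 5, 5 and 2 of 14, 16 and 13 in liver for WY14643, GW501516 and rosiglitazone, 1 of 11, 1 of 13 and 0 of 18 in heart, 8 of 20, 6 of 15 and 2 of 15 in kidney, and 0 of 22, 0 of 7 and 0 of 13 in muscle.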

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

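Of the tests in this part, those of a clock change in one direction on every day, of the day-8 shift of each compound, of counts with clock components as covariates, of kidney replicate 1, of skeletal muscle replicates 2 and 3 and of liver RNA beside Cyp4a14 were chosen after the results were seen.

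Clock genes differed between treated and vehicle animals of the same day. In liver 8 clock genes called in opposite directions on 2 days argued against a clock change by WY14643 in the same direction every day. It stays open in other tissues (1 in heart, 0 in kidney and muscle). For GW501516 and rosiglitazone the count of 0 is no test, as limma called 0 clock genes on day 4. Collection at different times of day stays open. Deviations of the clock score within groups were shared by the tissues of an animal (mean correlation 0.75). The day-8 shift of vehicle animals (1.33) was in size 2.89 times that of treated animals pooled (-0.461), which ran the other way. WY14643 animals shifted by -1.02 (SE 0.297), GW501516 by 0.115 (SE 0.15) and rosiglitazone by -0.476 (SE 0.224). A shift of vehicle animals alone does not cover WY14643. With clock components as covariates rosiglitazone had 31 calls in liver instead of 2946. The score and the treatment overlap, so the loss of calls does not tell the hour of collection from treatment. An effect of the compounds on feeding or the clock was not tested and stays open too.

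GW501516 called 1703 genes in kidney on day 8, and replicate 1 of that group stood apart from the others (r 0.9245 with the rest of its group). Collection at different times of day stays open. Clock components gave 3664 genes but came from the same arrays, replicate 1 included, so the count cannot test it. Replicate 1 stays open too, since 137 genes were called without it. Chance could not be excluded: 14 of 100 splits of the samples called as many, and the highest other split called 5571, which points to a structure of the samples other than treatment. What sets replicate 1 apart, in technique or in the animal, was not tested.

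Skeletal muscle called 608 genes with WY14643 on day 4, and Cyp4a14 rose with WY14643 in heart, kidney and skeletal muscle and with GW501516 in heart and kidney. Liver RNA was argued against for kidney, where deviations of Cyp4a14 and of hepatocyte markers from their group means did not go together over the WY14643 arrays (-0.00535) and ran opposite over the GW501516 arrays (-0.682). In heart (0.951, and 0.942 with GW501516) and skeletal muscle (0.989) they did, and Alb ran from 5.21 to 13.6 and from 3.89 to 13.0 over the arrays there, so RNA of liver may account for Cyp4a14 in these arrays. For the 608 genes, replicates 2 and 3 (2 genes without them), RNA of other cell types (median change 3.32 for the list that moved most) and collection at different times of day (52 genes with clock components as covariates; median absolute change 0.571 without and 0.462 with them, median standard error 0.15 and 0.17) stay open. Of the 13 hepatocyte markers, 12 in heart and 6 in skeletal muscle lay over the 40th percentile of intensity and 8 stand in another list too, and a rise of Cyp4a14 within heart or muscle cells was not tested.

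Dixon's test was made in 48 groups for 3 measures, and chance alone marks about 1 in 20. Arrays far from their group by correlation with it were, in liver, GW501516 day 8 replicate 1 (0.9897), vehicle day 15 replicate 10 (0.9901) and WY14643 day 8 replicate 1 (0.9893), in heart rosiglitazone day 4 replicate 1 (0.953), and in kidney GW501516 day 8 replicate 1 (0.9245), vehicle day 8 replicate 5 (0.992) and WY14643 day 4 replicate 2 (0.9823). In skeletal muscle these were GW501516 day 8 replicate 2 (0.9805), rosiglitazone day 15 replicate 4 (0.9746), rosiglitazone day 4 replicate 3 (0.9829) and vehicle day 8 replicate 3 (0.981). By clock score they were heart rosiglitazone day 4 replicate 2 (0.5593), kidney rosiglitazone day 4 replicate 2 (2.47), kidney vehicle day 8 replicate 7 (3.748), kidney WY14643 day 4 replicate 3 (-0.5286) and liver rosiglitazone day 4 replicate 2 (1.157). By mean level of the panel they were kidney WY14643 day 4 replicate 2 (10.13), liver GW501516 day 15 replicate 1 (10.18) and liver WY14643 day 4 replicate 2 (10.93).

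Responses on days 15 and 4 differed by a test of the difference at 137 genes (WY14643) and 24 (rosiglitazone) in liver, 50 (WY14643) and 3 (GW501516) in heart, 4 (WY14643) and 2 (GW501516) in kidney and 1 (rosiglitazone) in skeletal muscle. Between liver and another tissue, panel responses differed in 48 (WY14643), 46 (GW501516) and 33 (rosiglitazone) tests. Signal also lay in probe sets without a single named gene, which the comparisons did not use: of 10092 such probe sets, WY14643, GW501516 and rosiglitazone changed 351, 520 and 596 in liver, 73, 346 and 378 in heart, 33, 287 and 47 in kidney, and 8, 84 and 79 in skeletal muscle.

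Each count was set against 100 splits of the same samples, the real one included, with the highest count of the others in brackets. The line set in advance was fewer than 5 of 100 splits giving as many, at which some of many results pass by chance. Passing it does not exclude chance. In liver 1 split of 100, the real one, gave each count. The mean over days gave 2044 (351) with WY14643, 2532 (7) with GW501516 and 2946 (147) with rosiglitazone. Days 4, 8 and 15 gave in turn 1173 (175), 1149 (4) and 521 (49), then 245 (4), 1607 (40) and 804 (138). Rosiglitazone gave 224 (10), 2326 (2092) and 972 (145). Lists gave 5 (2), 5 (2) and 2 (1), the change between days 137 (134) with WY14643 and 24 (14) with rosiglitazone, the compound differences 827 (565), 3199 (706) and 653 (1), and vehicle between days 739 (32). Limma called 0 genes (1) between days for GW501516, matched by 100 splits. Panel differences between tissues gave 48 (32), 46 (30) and 33 (7), 1 split each.

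In kidney the line was passed for the mean over days with 316 (0), 1236 (51) and 276 (1). It was also passed for days with 50 (11), 92 (1) and 99 (6), then 31 (25) and 242 (6) on days 4 and 15, then 137 (1) and 24 (1) on days 8 and 15. The same held for lists with 8 (1) and 6 (1) and for the change between days with 4 (5, 2 splits) and 2 (1). Compound differences with 244 (88), 355 (2) and 203 (35) and vehicle with 159 (2) passed too. Another split gave more than the 4 between days. The line was not passed for the rosiglitazone lists with 2 (2, 5 splits). For rosiglitazone limma called 0 (1) on day 4 and 0 (1) between days, matched by 100 splits.

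In heart the mean over days passed the line with 262 (220), 759 (845, 2 splits) and 1367 (105). WY14643 passed on days 4 and 8 with 46 (4) and 79 (1). GW501516 passed on days 4, 8 and 15 with 23 (1), 297 (12) and 139 (2127, 2 splits). Rosiglitazone did with 40 (102, 4 splits), 760 (135) and 199 (1416, 2 splits). GW501516 between days with 3 (5, 3 splits) and vehicle with 71 (818, 2 splits) passed too. Compound differences did with 552 (71), 1114 (95) and 8 (1). The line was not passed for WY14643 on day 15 with 613 (1974, 8 splits) and between days with 50 (3907, 17 splits). Nor was it for lists, 1 (1, 9 splits) with WY14643 and 1 (6, 5 splits) with GW501516. Rosiglitazone lists with 0 (3) and its change between days with 0 (98) in limma were matched by 100 splits. Splits that called several times the real count, such as 3907, point to a structure of the heart samples.

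In skeletal muscle the mean over days passed the line with 19 (3326, 2 splits), 156 (1) and 301 (12). WY14643 passed on days 4 and 8 with 608 (316) and 7 (661, 2 splits). GW501516 passed on days 8 and 15 with 71 (1) and 12 (40, 3 splits). Rosiglitazone on day 8 with 155 (4) and compound differences with 104 (3) and 12 (1) passed too. The line was not passed for WY14643 on day 15 with 3 (112, 7 splits) and GW501516 on day 4 with 3 (165, 8 splits). Rosiglitazone on day 15 with 44 (169, 6 splits) and between days with 1 (286, 9 splits) did not pass. Nor did WY14643 minus rosiglitazone with 7 (2199, 5 splits) and vehicle with 1 (4, 5 splits). Counts of 0 from limma and camera were matched by 100 splits: lists with 0 (1), 0 (4) and 0 (1), the change between days with 0 (1882) for WY14643 and 0 (0) for GW501516, and rosiglitazone on day 4 with 0 (15). Counts such as 3326 and 2199 in other splits point to a structure of the muscle samples.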

How the results depend on the processing

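The alternatives with days 4 and 15 only, clock components, marker scores and lists without a pair of odd arrays were chosen after the results were seen. Fold changes refer to log2 and counts to genes or lists called, and a count does not say which genes. A count was taken as moved when it differed more than 1.5-fold from the reported one, and unless a cause is given, the cause was not tested.

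Subtracting each array's median (12 of 12 counts), the mean of a gene's probe sets (12 of 12) and unpaired tissue differences (3 of 3) moved no count. The other alternatives left 98 results in place and moved 5 (quantile normalization), or 89 and 14 (dim genes left out), 66 and 22 (replicate block), 4 and 8 (array weights), 8 and 4 (only the 2 treatments compared), 5 and 7 (all vehicle arrays), 3 and 9 (fry), 0 and 12 (preset correlation), 2 and 10 (days 4 and 15), 12 and 12 (clock components), 37 and 11 (marker scores) and 10 and 2 (lists without the odd arrays). Of 771 called fold changes of named genes, the direction and call stood for 746 with quantile normalization, 743 with array weights, 716 with only the 2 treatments, 707 with medians subtracted, 690 with the mean of probe sets, 613 with the replicate block, 452 with days 4 and 15 and 347 with clock components. Of those tested, 708 stood with dim genes left out and 377 with marker scores. In 32891 fits with 1 array left out the call of a named gene stood, and in 1804 it ended. No direction was reversed except with clock components (53) and with days 4 and 15 (3).

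Quantile normalization gave 132 genes with rosiglitazone in liver on day 4, 21 with GW501516 in skeletal muscle on day 15, 1 for rosiglitazone in heart and 1 for GW501516 in kidney between days 15 and 4, and 1 list for rosiglitazone in liver; the cause was not tested. Leaving out dim genes tested fewer genes. It gave between days 15 and 4 2 genes (GW501516 in liver), 122 (WY14643 in heart), 1 (rosiglitazone in heart), 1 (GW501516 in kidney) and 1 (WY14643 in skeletal muscle). For GW501516 it gave 49 in kidney and 15 in skeletal muscle on day 4, 22 in skeletal muscle on day 15, and 3 for GW501516 minus rosiglitazone in heart. Correlations of responses were then 0.456 (GW501516 and rosiglitazone in heart), 0.392 (WY14643 and GW501516 in kidney), and in skeletal muscle 0.374 (WY14643 and rosiglitazone) and 0.198 (GW501516 and rosiglitazone), and 0 lists were called by camera for rosiglitazone in liver.

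The replicate block took arrays of equal number as a block, but deviations of such arrays did not go together (median correlation -0.0213 in liver, 0.0255 in heart, 0.00278 in kidney and 0.0506 in skeletal muscle over 45 pairs each), so numbers pair no animals across groups. With it, between days 15 and 4, GW501516 gave 1 gene in liver and 5 in kidney and WY14643 gave 88 in heart. In heart WY14643 gave 22 on day 4 and 125 on day 8, GW501516 501 over the days and rosiglitazone 22 on day 4. In kidney WY14643 gave 33 on day 4, GW501516 409 over the days, 555 on day 8 and 156 on day 15, and rosiglitazone 2 on day 4. In skeletal muscle WY14643 gave 61 over the days, 24 on day 8 and, in limma, 0 on day 15, rosiglitazone 629 over the days, 380 on day 8 and 1.1e2 (35 up and 73 down) on day 15, and WY14643 minus rosiglitazone 4. Lists were 1 (rosiglitazone in liver), 1 (rosiglitazone in heart) and 5 (WY14643 in kidney), and the cause was not tested.

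Array weights gave for WY14643, GW501516 and rosiglitazone 680, 1267 and 2070 genes in heart and 34, 458 and 643 in skeletal muscle, and 634 (WY14643) and 737 (rosiglitazone) in kidney. Comparing only the 2 treatments gave 509, 756 and 559 in kidney and 10 with WY14643 in skeletal muscle. The cause was not tested for either. With all vehicle arrays used for both compounds, which then share them, correlations were 0.418 (WY14643 and rosiglitazone in heart). For WY14643 and GW501516, WY14643 and rosiglitazone, and GW501516 and rosiglitazone in turn they were 0.465, 0.302 and 0.411 in kidney and -0.0814, 0.418 and 0.382 in skeletal muscle.

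The number of lists called depended on the test. The preset correlation of 0.01, which is below most estimated ones, gave for WY14643, GW501516 and rosiglitazone 14, 16 and 13 lists in liver, 11, 13 and 18 in heart, 20, 15 and 15 in kidney and 22, 7 and 13 in skeletal muscle. Fry, which tests another null, gave 14, 17 and 14 in liver, 3, 3 and 6 in heart, 12 (GW501516) and 8 (rosiglitazone) in kidney and 3 (WY14643) in skeletal muscle. Without the odd arrays camera gave 1 list for rosiglitazone in liver and 5 for WY14643 in kidney; in liver, where no array was left out, only the adjustment over all tissues had changed, and in kidney the cause was not tested. Marker scores as covariates gave lists of 2 (GW501516 in heart), 1 (rosiglitazone in heart), 4 (rosiglitazone in kidney) and 3 (GW501516 in skeletal muscle), and 30 genes with WY14643 in kidney on day 4. In skeletal muscle they gave 45 and 8 with WY14643 on days 4 and 15, 12 and 27 with GW501516 and 1 and 14 with rosiglitazone, and the cause was not tested.

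With days 4 and 15 only, which leaves fewer samples, limma called for the mean over days 1344 (GW501516) and 1823 (rosiglitazone) in liver and 202 and 399 in heart. It called 175 (WY14643), 321 (GW501516) and 29 (rosiglitazone) in kidney and 32, 26 and 16 in skeletal muscle. With WY14643 in liver the direction was reversed for Tk1 -0.0905, Npas2 0.33 and Ciart -0.0652, where day 8 carried the reported direction.

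With clock components as covariates, limma called 485 (GW501516) and 31 (rosiglitazone) in liver, 174 (WY14643), 221 (GW501516) and 251 (rosiglitazone) in heart and 53 (GW501516) and 84 (rosiglitazone) in skeletal muscle. Camera called 0 lists for rosiglitazone in liver, 0 for WY14643 and 0 for GW501516 in heart, and in kidney 5 (WY14643) and 1 (rosiglitazone). Part of the loss came from wider standard errors, as with rosiglitazone in liver (median 0.0592 without and 0.119 with them) and heart (0.053 and 0.103). Fold changes of 53 named genes changed sign, and the cause was not tested. With GW501516 in liver these were Zbtb16 -0.13, Per1 -0.34 and Sdf2l1 0.0175. With rosiglitazone in liver these were Creb3l3 -0.0590, Pgd 0.00114, Gstm4 0.19, Rxrb -0.0296, Saa4 -0.0292, Mvd 0.12, Sqle 0.39, Mvk 0.0438, Ciart -0.0595, Zbtb16 -0.0154, Foxo1 -0.0220, Pdk2 -0.0126, Hspb8 -0.0607, Hspd1 -0.0281, Rsad2 0.0852, Abcg5 -0.0913, Atf5 0.0214, Pdia6 0.0569, Cyp2b10 -0.30, Alas1 -0.77, Nr1i2 -0.00446, Slc4a1 0.00963 and S100a9 0.47. With GW501516 in heart these were Rcan1 0.0725, Per2 -0.13, Ciart -0.0214, Mid1ip1 -0.0266, Fkbp5 -0.0273 and Flt1 -0.0766. With rosiglitazone in heart these were Fabp7 0.15, Cyp27a1 -0.0411, Rcan1 0.0227, Stard4 0.15, Srebf2 0.0518, Per2 -0.28, Hlf -0.0607, Mid1ip1 -0.13, Fkbp5 -0.0278, Herpud1 -0.0964, Flt1 -0.22, Col1a1 0.43, Loxl1 0.47, Col3a1 0.31 and Col6a1 0.34. With rosiglitazone in kidney these were Nfil3 -0.21, Ppara -0.0107, Tsc22d3 -0.22, Foxo1 -0.00200, Herpud1 -0.12 and Alas1 -0.17.

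With 1 array left out at a time, 57 of 79 counts moved in at least 1 fit, and 22 moved in none, among them the means over days of the 3 compounds in liver and kidney and of GW501516 and rosiglitazone in heart and skeletal muscle. The cause was not tested; the ranges below name the array where a count lay more than 1.5-fold from the reported one. In liver, WY14643 gave on day 4 672 (without replicate 2) to 1426, on day 8 721 (without replicate 4) to 1237, on day 15 326 (without replicate 5) to 566 and between days 61 (without day 15 replicate 3) to 194. GW501516 gave on day 4 128 (without replicate 4) to 305, on day 8 938 (without replicate 3) to 1776, on day 15 518 (without replicate 2) to 859 and between days 0 to 4 (without vehicle day 15 replicate 1). Rosiglitazone gave on day 4 65 (without replicate 5) to 285, on day 8 1451 (without replicate 4) to 2587, on day 15 615 (without replicate 5) to 1061 and between days 2 (without day 15 replicate 2) to 50 (without day 15 replicate 1). Differences gave for vehicle between days 400 (without day 15 replicate 7) to 856. In heart, WY14643 gave over the days 113 (without day 4 replicate 2) to 455 (without vehicle day 15 replicate 8), on day 4 7 (without replicate 2) to 217 (without replicate 3), on day 8 34 (without replicate 2) to 98, on day 15 12 (without replicate 4) to 1572 (without vehicle replicate 8) and between days 11 (without day 15 replicate 4) to 408 (without day 15 replicate 5). GW501516 gave on day 4 6 (without replicate 1) to 29, on day 15 81 (without replicate 2) to 165 and between days 0 (without day 15 replicate 3) to 4. Rosiglitazone gave on day 4 2 (without replicate 1) to 559 (without replicate 2), on day 15 114 (without replicate 4) to 233 and between days 0 to 3 (without vehicle day 15 replicate 5). Differences gave for WY14643 minus GW501516 299 (without WY14643 day 15 replicate 4) to 834 (without WY14643 day 15 replicate 5), WY14643 minus rosiglitazone 662 (without WY14643 day 15 replicate 4) to 1591, GW501516 minus rosiglitazone 6 to 36 (without rosiglitazone day 4 replicate 1) and vehicle between days 35 (without day 4 replicate 6) to 165 (without day 15 replicate 2). In kidney, WY14643 gave on day 4 17 (without replicate 2) to 76 (without replicate 3), on day 8 58 (without replicate 2) to 96 and on day 15 55 (without replicate 5) to 124. GW501516 gave on day 4 17 (without replicate 1) to 38, on day 8 137 (without replicate 1) to 3621 (without replicate 3), on day 15 99 (without replicate 5) to 505 (without replicate 1) and between days 0 (without day 15 replicate 2) to 6 (without day 15 replicate 1). Rosiglitazone gave on day 8 62 (without replicate 4) to 152, on day 15 12 (without replicate 5) to 28 and between days 0 to 1 (without vehicle day 15 replicate 2). Differences gave for WY14643 minus GW501516 141 (without WY14643 day 15 replicate 5) to 540 (without GW501516 day 8 replicate 2), GW501516 minus rosiglitazone 145 to 336 (without GW501516 day 8 replicate 1) and vehicle between days 60 (without day 15 replicate 1) to 398 (without day 4 replicate 10). In skeletal muscle, WY14643 gave over the days 10 (without day 15 replicate 2) to 81 (without day 4 replicate 1), on day 4 149 (without replicate 3) to 1195 (without replicate 4), on day 8 1 (without replicate 4) to 9, on day 15 0 (without replicate 5) to 7 (without replicate 1) and between days 0 to 23 (without day 4 replicate 5). GW501516 gave on day 4 1 (without replicate 1) to 10 (without vehicle replicate 3), on day 8 35 (without replicate 1) to 72 and on day 15 6 (without replicate 2) to 17. Rosiglitazone gave on day 4 0 to 1 (without vehicle replicate 3), on day 8 88 (without replicate 5) to 161, on day 15 9 (without replicate 2) to 52 and between days 0 (without day 15 replicate 4) to 1. Differences gave for WY14643 minus GW501516 51 (without GW501516 day 15 replicate 5) to 168 (without GW501516 day 15 replicate 1), WY14643 minus rosiglitazone 3 (without rosiglitazone day 4 replicate 1) to 11 (without rosiglitazone day 4 replicate 5), GW501516 minus rosiglitazone 6 (without GW501516 day 15 replicate 2) to 20 (without GW501516 day 15 replicate 1) and vehicle between days 1 to 3 (without day 4 replicate 2).

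Signal over background limited what could be seen: the 5th percentile of intensity lay between 2.39 and 2.58 in liver, 2.97 and 3.15 in heart, 1.7 and 2.44 in kidney and 1.52 and 1.74 in skeletal muscle. For genes under the 40th percentile a missing call does not tell a small change from none.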

Other observations

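Genes also moved in animals that received vehicle alone, between day 4 and day 15. In liver, Corin (2.58 ± 0.78), Arntl (1.68 ± 0.33) and Npas2 (1.60 ± 0.30) were higher on day 15, and Nmrk1 (-1.51 ± 0.29), Ciart (-1.46 ± 0.33) and the deubiquitinase gene Usp2 (-1.40 ± 0.28) were lower (log2 fold change ± SE). Of PPAR target genes, Ehhadh (0.27 ± 0.080) and Plin2 (0.22 ± 0.065) were called higher and Fabp1 (-0.09 ± 0.028) lower, while larger differences such as Pdk4 (0.88 ± 0.31, adjusted p 0.0888) did not pass. In heart, Arntl (1.33 ± 0.22), the fatty acid carrier gene Fabp7 (1.0 ± 0.24), Tmem171 (0.67 ± 0.15) and the metalloprotease gene Adam19 (0.63 ± 0.15) were higher, and Per3 (-0.63 ± 0.12) and Htra4 (-0.68 ± 0.17) lower. In kidney, Npas2 (1.35 ± 0.27), the spindle gene Prc1 (0.84 ± 0.19), the vasopressin receptor gene Avpr1a (0.79 ± 0.12) and Fabp7 (0.79 ± 0.14) were higher, and Cry1 (-0.89 ± 0.17) and the uridine phosphorylase gene Upp2 (-0.87 ± 0.15) lower. These were the 6 largest called differences per tissue and the called panel genes, each from 10 against 10 arrays in limma.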
